A study of Oryza sativa with 66 samples.

How the data were processed

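Total RNA from rice (Oryza sativa) was measured on 66 one-colour Agilent arrays in 22 groups of 3. Anthers of 5 strains (Nipponbare, T65, Hoshinoyume, A58 and Silewah) were represented without treatment (C0), after 1 day (C1) and 3 days (C3) at 12 °C, and 1 day after the end of the 4 days of cool treatment (C5, day 5). Leaves of untreated Nipponbare and T65 were also measured. Plants were grown at 25 °C by day and 19 °C by night and treated at the booting stage, per the labels. The series design names the 3 arrays of a group biological replicates. The p-values of the linear models rest on the spread between replicates pooled over all groups of a fit, not on that of the compared groups alone. C0 had no treatment and the age of those anthers relative to C1, C3 and C5 was not given in the sources used here, so time and development run along with the treatment in each comparison against C0.

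Each array held 45220 spots, of which 1417 were controls and 43803 were probes. The probe names in the files gave 11819 probes for genes, 31120 for repeats and 864 for the precursors of microRNAs (454 precursors, on the sense or the antisense strand). Of the repeat probes, 30648 carried a TIGR repeat code (16762 sequences) and 472 a RetrOryza name. The codes are TEMT for miniature inverted-repeat transposable elements (MITEs), TETN for transposons, TERT for retrotransposons, CMCM for centromere repeats, OTOT for other repeats, RGRR for ribosomal DNA and TRTM for telomere repeats. Of the gene probes, 2753 were named by a locus of the RAP annotation (2649 loci), 7125 by an AK cDNA accession and 1941 by another accession. The files do not pair these identifiers with gene symbols, and 0 gene probes matched the reference gene table, so such probes are given by their identifier and no genome position was used.

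The scanner files hold spot intensity on a linear scale after background subtraction, made by the authors with Agilent Feature Extraction, version 10.7.3.1 per the file headers and 9.5.3.1 per the submitters' processing notes. The array design is on the build IRGSP5, per the file headers. The deposited series matrix holds log2 values, which differed from the log2 of the processed intensity by at most 3e-06 on every array, so they carry no centring and no scaling between arrays. The medians of its columns lay between 4.476 and 6.398. No other step of the authors is given in the sources used here.

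From the scanner files, log2 of the processed intensity minus each array's 75th percentile was computed. Spots marked as outliers by the scanner software (at most 153 probes on an array) were left out. There were 0 saturated probes. Between 52.58% and 75.63% of the probes were well above background on an array, and the 75th percentile of the signal lay between 156.5 and 526.49. The number of arrays per group limits the precision. A probe was tested where it was well above background on all 3 arrays of at least 1 group and had at least 2 values in every group, which left 32063 probes in the anther fit (60 arrays) and 31574 in the leaf fit (12 arrays). All probes of a gene were kept apart. Linear models with group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust). P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe was called at an adjusted p under 0.05 and at least a 2-fold change. Repeat probes changed on any day, strain differences in untreated anthers and interactions of strain with day were tested with moderated F tests, and the largest difference between the fitted values had to reach 2-fold. Log2 changes are given with the standard error of that fit. Where a probe was not well above background on any array of the dimmer group, the change is given as "at least" a fold. It sets the brighter group's mean of normalized log2 values against the mean over the dimmer group's arrays of the higher of that array's lowest signal among probes well above background and the probe's own signal.

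Classes of probes were tested with camera at a preset correlation of 0.01 and with an estimated correlation. After the data had been seen, the means of classes and families were also tested by exchanging arrays between days within strains, without regard to slides (100000 permutations, two-sided, smallest possible p 1e-05). For the counts, other splits of the same arrays were fitted, all 10 for 3 against 3 arrays and otherwise 100 draws with a fixed seed. The draws for repeats on any day and for the interactions were first set at 40 and 60 and were extended to 100 after the first counts had been seen. For the interactions, the residuals of a model with strain and day were exchanged within strains, and missing values were filled with the probe's mean. Slides and scan sessions were read from the scan records (19 slides, 7 sessions). Each strain was scanned in 1 session except Nipponbare, which spans sessions 1 to 3, so differences between strains cannot be told apart from session. T65 C0 lay alone on slide 11, so slide and group cannot be told apart for T65 against C0. In Hoshinoyume, A58 and Silewah no slide held C0 together with C3 or C5, nor did any hold both C0 and C3 of Nipponbare. In those comparisons slide and group are linked only through arrays of other days.

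Named probes followed a rule written before the data were examined, as were the main design, the gene lists and the first set of alternatives. The rule took the 5 highest and 5 lowest probes called in the same direction in all 5 strains on a day. For C5 against C3 it took the 4 highest and 4 lowest called in at least 4 strains, and for each strain the 2 highest and 2 lowest C3 changes relative to the other strains among interaction calls. It also took up to 4 members of each list, the 5 highest and 5 lowest leaf calls shared by both strains, the 6 largest strain differences in untreated anthers and the 2 largest C3 changes of each repeat class. RetrOryza elements and microRNA precursors (6 each) were added after the probe names were seen and before any signal was compared. Probes with only an accession or locus count as unnamed, and few of them are given. Of the classes and families given as summaries over all their members, the MIR2118 precursors, the centromere satellite and the MITE family TEMT017 were singled out after their values were seen. The 10 lists of loci (abscisic acid, antioxidant, circadian clock, cold effectors, cold transcription factors, gibberellin, meiosis, silencing and chromatin, sugar and starch, tapetum and exine) held 135 loci, of which 10 had a probe. The 13 lists defined by keywords in gene descriptions (among them ribosomal protein, heat shock, peroxidase and photosynthesis, the marker of green tissue) matched 0 probes, since the files hold no descriptions.

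That first set was quantile normalization, normexp (offset 50) with quantile normalization, the matrix values, no filter and a stricter filter (well above background on a share of at least 0.5 of the arrays), slide as a random or fixed block, the replicate number as a block, array weights, only the arrays compared, and each array left out in turn. The normexp step used the median spot signal, because the files used here hold no mean signal. Scaling to spike-in spots (224 spots well above background on every array), scan session as a block, the leading within-group component as a covariate, fits without Nipponbare, the omission of arrays for named probes and the overlaps under other choices were chosen after seeing the data. Array weights were computed gene by gene, because the method chosen first stopped before it converged. The mean of several probes per gene was not run, since probes were not paired to genes. The fits were tested on simulated data with 200 of 32063 probes changed and noise drawn independently per probe. For A58 C3 against C0, 65% of changes of 1.5 log2 and 90% of changes of 3 log2 were recovered, with 8 false calls. For the C3 interaction the shares were 53% and 76%. The simulation gave all groups of a probe the same SD and no correlation within slides, so its false calls do not show those of the real arrays. Tables were read with Python 3.11.15 (pandas 2.3.3, NumPy 2.4.6) and the data.table package, version 1.17.8, and plots were drawn with matplotlib 3.10.9.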

Results

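Anthers of 5 rice strains were profiled before, during and after 4 days at 12 °C around the early microspore stage, when pollen development is sensitive to cold. Silewah is a tropical line. The arrays held probes for genes, for repeats of the genome and for microRNA precursors, and each of the 22 groups had 3 arrays. Of the probes, 52.58% (Hoshinoyume C1 replicate 2) to 75.63% (Nipponbare C0 replicate 2) were well above background. Replicates of a group correlated with r of at least 0.863 across probes, the lowest value belonging to Nipponbare C0 replicates 2 and 3. The 2 most alike arrays, A58 C3 replicates 1 and 2, still differed with an SD of 0.335 log2, so all arrays were counted as separate samples.

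The first question was which transcripts responded to cool treatment in several strains. AK060548, a cDNA whose gene the files do not name, rose after 1 day by 6.37 log2 in Nipponbare, 4.68 in T65, 6.21 in A58 and 4.57 in Silewah (standard error 0.98, 3 arrays per group). AK061678 rose by 2.73, 2.85, 2.46 and 3.16 log2 in the same 4 strains (standard error 0.54). These 8 calls were kept whichever array was left out. AK068491 was the only probe called in all 5 strains at C1, with log2 changes of −1.18 in Nipponbare, −1.34 in T65, −1.47 in Hoshinoyume, −1.17 in A58 and −1.63 in Silewah (standard error 0.24). Its call ended in Nipponbare without C1 replicate 1 (−0.84) and in Hoshinoyume without C1 replicate 2. Under limma, 38 probes, all for genes, were higher at C1 in at least 4 strains and 30 were lower, 29 of them for genes, against 23 and 19 with normexp, 12 and 3 on the matrix values, 4 and 4 with spike-in scaling and 6 and 2 with slide as a random block.

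After 3 days, AK060548 stood 6.65 log2 above C0 in Nipponbare, 5.64 in T65, 4.42 in Hoshinoyume, 6.08 in A58 and 4.55 in Silewah (standard error 0.98). AK063972 rose by 1.94, 1.87, 1.85, 1.74 and 2.41 log2 in these strains (standard error 0.37). Os01t0600900-03 fell in all 5, with changes of −3.14, −3.92, −4.08, −2.49 and −3.24 log2 (standard error 0.55). A MITE, ORSgTEMT05200103 on the sense strand, was also higher in all 5 strains, by 2.21 log2 in Nipponbare, 2.33 in T65, 2.25 in Hoshinoyume, 1.55 in A58 and 2.33 in Silewah (standard error 0.39). In all 5 strains 11 probes were higher at C3 (9 for genes, 2 for repeats) and 6 were lower (all for genes), against 5 and 5 with normexp, 3 and 1 on the matrix values, 1 and 2 with spike-in scaling and 1 and 0 with slide as a random block. The A58 call of ORSgTEMT05200103 was lost in each of the 6 omissions of an array (1.38 to 1.67 log2). The Hoshinoyume call of AK060548 was lost without C0 replicate 1, C0 replicate 2 or C3 replicate 2 (3.47 to 6.31 log2 over the omissions), that of AK063972 without C0 replicate 1 or 2, and A58 lost AK063972 without C3 replicate 1 and Os01t0600900-03 without C0 replicate 2 or C3 replicate 1.

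Overlaps of calls between strains, which had separate controls, were set against those of independent lists. At C3, T65 and Silewah shared 126 higher probes (6.35 expected) and 79 lower probes (3.29 expected), and 1 probe went opposite ways. At C1, A58 and Silewah shared 161 higher probes (5.51 expected) and 73 lower (6.55 expected), with 0 opposite. These overlaps shrank under other choices, for T65 and Silewah at C3 to 20 higher and 46 lower on the matrix values (1.27 and 12.2 expected), 8 and 16 with spike-in scaling (0.0365 and 0.920) and 39 and 18 with slide as a random block (0.449 and 0.0944). For A58 and Silewah at C1 they shrank to 53 and 19 on the matrix values (0.894 and 0.886 expected), 6 and 35 with spike-in scaling (0.0213 and 0.965) and 99 and 42 with slide as a random block (2.47 and 2.22). Nipponbare and T65 shared 97 higher and 108 lower probes at C3, against 31.8 and 20.8 expected, while 31 went opposite ways, but on the matrix values 22 and 222 (3.32 and 99.0 expected) with 415 opposite, with spike-in scaling 12 and 52 (0.945 and 5.46) with 32 opposite, and with slide as a random block 16 and 23 (2.74 and 0.830) with 0 opposite. At C5 this pair shared 0 probes in either direction and 53 were called in opposite directions, against 1 with spike-in scaling and 0 with slide as a random block. The log2 changes of Nipponbare and T65 correlated with r −0.05 at C3 and −0.35 at C5, and those of T65 and Silewah with r 0.54 at C3, across probes, which are not independent replicates.

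Of the 135 loci on the 10 lists, 10 had a probe. PRR1, a pseudo-response regulator of the circadian clock, rose by 1.18 log2 in A58 at C1 (standard error 0.29, adjusted p 0.00994) and by 1.19 in Silewah at C3 (adjusted p 0.00869). ABA8ox1, an abscisic acid 8'-hydroxylase that breaks down the hormone, fell in Silewah with changes of −2.36 log2 at C1 (standard error 0.43, adjusted p 0.00041) and −1.90 at C3 (adjusted p 0.00429), and both calls were kept in all omissions. DREB1H, a gene of the cold-responsive DREB1 family, had a change of −1.07 log2 in Nipponbare at C1 (standard error 0.23, adjusted p 0.00145). RAB16B, a dehydrin gene responsive to abscisic acid, rose by 5.35 log2 in Nipponbare at C5 (standard error 1.54, adjusted p 0.0252). GAMYB, the gibberellin-related regulator of anther development, rose by 1.16 log2 (standard error 0.29, adjusted p 0.0112) and DCL3b, a Dicer-like gene, by 1.08 (standard error 0.32, adjusted p 0.0364) in Silewah at C3.

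The tapetal cysteine protease gene CP1 was higher by 3.06 log2 in Nipponbare at C1 (standard error 1.06, adjusted p 0.0394) and lower in T65 at C5 with a change of −3.58 (adjusted p 0.0439). The meiotic gene HEI10 was at least 1.56-fold higher at C5 than at C3 in Silewah (adjusted p 0.00529). PRR1 was also called in Hoshinoyume at C3 (1.05 log2) and Silewah at C1 (1.11 log2), and ABA8ox1 in A58 at C3 (−1.82 log2, adjusted p 0.0155). MYB3R-2, of the cold transcription factor list, and P5CS, a proline synthesis gene, were called in none of the 20 comparisons. Adjusted over the list alone, the calls also held CP1 in Nipponbare at C3, ABA8ox1 in Hoshinoyume at C3 and C5, HEI10 in Silewah at C3, and, for C5 against C3, RAB16B and ABA8ox1 in Nipponbare and ABA8ox1 in Silewah. With 1 array left out, the calls of DREB1H and RAB16B were each lost in 3 of 6 omissions, ABA8ox1 in A58 in 3 (−2.15 to −1.26 log2), CP1 in 4 in Nipponbare (2.09 to 3.80) and 5 in T65, DCL3b in 4 (0.85 to 1.28) and GAMYB without Silewah C3 replicate 3 (0.90). PRR1 lost its call in 5 omissions in Hoshinoyume, 2 in A58, and 3 at C1 (0.56 to 1.44) and 2 at C3 in Silewah. None of the 10 genes differed between strains at C3 by the interaction test, with adjusted p of 0.05002 for DREB1H and 0.101 for CP1.

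In Nipponbare, the cultivar of the rice reference genome, precursors of the microRNA family MIR2118 fell at C3. This family, whose members direct the cutting of long non-coding RNAs in the reproductive organs of grasses, was singled out after its values were seen. Of its 18 sense probes 17 were lower at C3 (median −2.80 log2, interquartile range −3.19 to −2.52), 11 at C5 (median −2.29) and 3 at C1 (median −0.93), and its mean at C3 was lower under all 5 scalings (−2.84 to −1.64). In each of the other 4 strains 0 of 18 were called by limma at C3 (at an unadjusted p under 0.05, 2 in A58 and 0 in the others). Mean changes there were −0.20 log2 in T65, −0.67 in Hoshinoyume, −0.69 in A58 and −0.07 in Silewah. Over the 5 strains the adjusted permutation p was 0.0199 (44 tests). These tests covered sets fixed after the data had been seen, so the adjustment leaves out the families they were picked from. osa-MIR2118r changed by −3.59 log2 at C3 (standard error 0.67) and osa-MIR2118o by −4.99 (standard error 0.97), both kept in every omission, with osa-MIR2118r at −2.37 without C0 replicate 3. The array means of the 18 probes were −2.35, −1.67 and 1.87 at C0, −2.71, −1.28 and −1.54 at C1, and −2.42, −4.15 and −4.09 at C3. Without C0 replicate 3 the family had 3 lower members at C3 (median −1.38), and without C3 replicate 2 or 3 it had 8 or 9. Scan session 1 held C0 replicate 1 and C3 replicate 1, whose means were −2.35 and −2.42. At C5 it had 2 lower members without C0 replicate 3 or C5 replicate 2 and 1 without C5 replicate 3. At C1 it had 9 without C0 replicate 1, 2 without C1 replicate 1, 1 without C0 replicate 2 or 3 and 0 without C1 replicate 2 or 3.

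**Figure D1:**
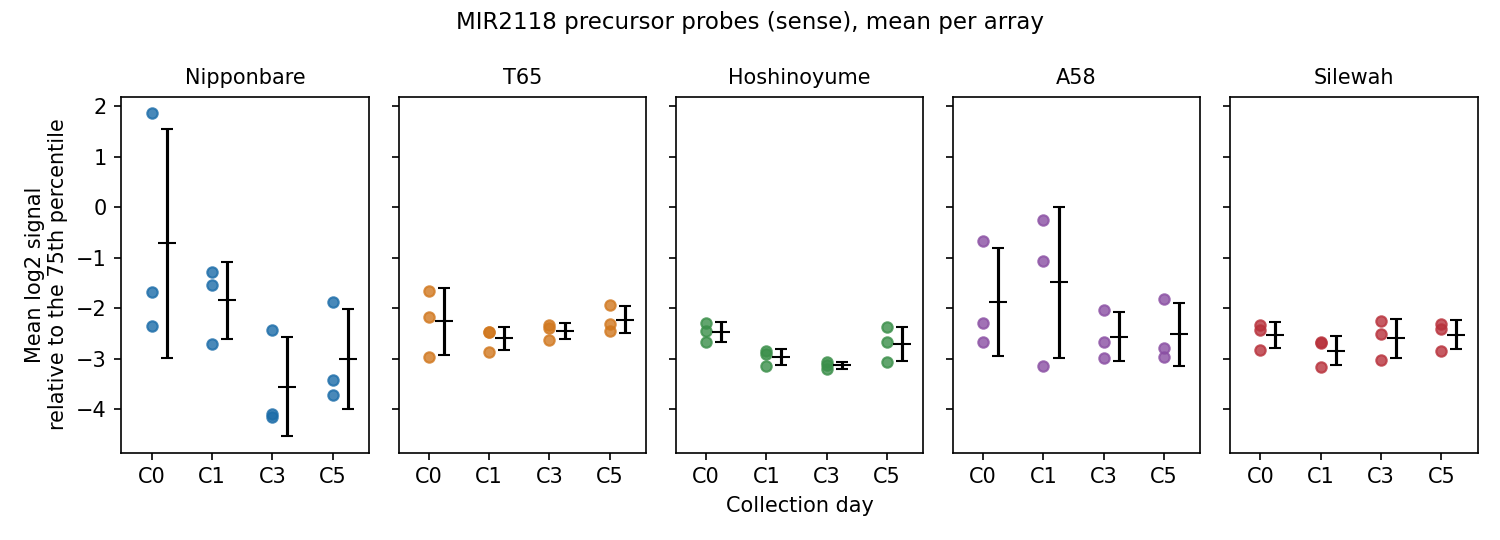
Mean normalized log2 signal of the 18 sense MIR2118 precursor probes on each anther array, by strain and day; points are arrays and bars the mean with the SD of 3 arrays. Nipponbare C0 replicate 3 (1.87) lies far above the other Nipponbare arrays, and Nipponbare C3 replicates 2 and 3 (−4.15 and −4.09) lie lowest in that strain.

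Other Nipponbare transcripts moved as well. osa-MIR395g, of a family tied to sulfate supply, was at least 8.71-fold higher at C3, and the ribosomal DNA probe ORSiRGRR00000365 had a change of −3.43 log2 (standard error 0.62), both kept in every omission. The retrotransposon osr1 was lower at C1 (−1.68 log2, standard error 0.32, kept in every omission) and at C3 (−1.33, lost without C0 replicate 3). Among the OTOT repeats 325 of 1096 were higher at C3, and the mean of the sense probes rose by 0.43 log2 under the main scaling and by 0.43 to 0.61 under the others. In total 2979 probes were called at C1 (1600 higher, 1379 lower), 3414 at C3 (1747 and 1667) and 1455 at C5 (510 and 945). Scaled to spike-ins the splits were 1639 and 120, 777 and 178, and 8 and 5, and on the matrix values 1206 and 547, 1401 and 700, and 150 and 19. At C5, normexp gave 694 higher and 282 lower.

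The Nipponbare anther arrays of scan session 3 had 56.75% to 67.40% of probes well above background, against 71.60% to 75.63% on its anther arrays of sessions 1 and 2, and no C0 array lay in session 3. With scan session as a block 1469 probes were called at C1, 2174 at C3 and 65 at C5, and with slide as a fixed block 1, 337 and 255. On the arrays of 1 session, which had entered the calls, 93.8% of the C1 calls and 88.5% of the C3 calls (session 1, 1 array each) and 95.6% of the C5 calls (session 2) had the same direction, and 49.1%, 38.1% and 48.4% did so at 2-fold or more. Without C0 replicate 2 the counts were 1274, 1378 and 513. Without C1 replicate 2 or 3 the C1 count was 1575 or 1426, without C3 replicate 2 or 3 the C3 count was 1432 or 1343, and without C5 replicate 1, 2 or 3 the C5 count was 4123, 331 or 131. Fits of only the 6 arrays compared called 7 at C1, 10 at C3 and 0 at C5.

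In T65, the microRNA precursor osa-MIR156d, of the family that targets SPL regulators, was at least 3.92-fold higher at C3 and kept its call in every omission. The antisense probe of the transposon ORSgTETN00100112, above background on 2 of the 3 T65 C0 arrays, was at least 1.05-fold lower at C1 and 1.25-fold lower at C3. In Nipponbare it fell as well (−2.37 and −2.24 log2, standard error 0.46), with each of these calls kept in every omission. At C1 352 MITE probes were higher and 29 lower, but the mean of the sense MITE probes, 0.20 log2 above C0, turned to −0.46 on the matrix values and −0.32 with spike-in scaling. Calls numbered 1123 at C1 (684 higher, 439 lower), 984 at C3 (583 and 401) and 837 at C5 (239 and 598). The matrix values gave 126 and 4207, 76 and 4536, and 40 and 2678, spike-in scaling 69 and 1726, 39 and 983, and 10 and 88, and normexp 220 and 243 at C3 and 85 and 396 at C5. The median of all probes moved from 0.09, 0.10 and 0.16 log2 to −0.57, −0.61 and −0.46 on the matrix values. Slide 11 held all T65 C0 arrays and no other array of this strain, and with slide as a random block the counts were 63, 109 and 0. Without C0 replicate 1 they were 592, 459 and 15. Other omissions gave 1714 at C1 (C1 replicate 3), 572, 648 and 1695 at C3 (C3 replicates 1, 2 and 3), and 129, 48 and 12 at C5 (C0 replicate 3, C5 replicates 1 and 2).

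In Hoshinoyume, a cultivar of northern Japan, AK063797 was at least 13.4-fold higher at C3, with its call kept in every omission. The retrotransposon osr2 was higher by 1.39 log2 at C3 (standard error 0.37), a call lost in 5 of 6 omissions (1.21 to 1.57). Calls numbered 16 at C1 (5 higher, 11 lower), 395 at C3 (227 and 168, of which 305 were gene probes and 87 repeat probes) and 1 at C5 (0 and 1). At C1 the matrix values gave 3 higher and 68 lower, normexp 12 and 9, quantile normalization 4 and 3, and spike-in scaling 2 and 2. At C5 quantile normalization gave 3 higher and 8 lower, and normexp 1 higher and 0 lower, while the replicate number as a block called 472 and array weights 1191. The C1 count was 7 without C0 replicate 2, 72 without C0 replicate 3, and 232, 0 and 496 without C1 replicates 1, 2 and 3. The C3 count was 72, 128 and 809 without C0 replicates 1, 2 and 3, and 215, 149 and 132 without C3 replicates 1, 2 and 3. The C5 count was 7, 4 and 10 without C0 replicates 1, 2 and 3 and 11, 29 and 25 without C5 replicates 1, 2 and 3.

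In A58, CI484934, an EST probe, rose by 3.36 log2 at C1 and 3.95 at C3 (standard error 0.57), and both calls were kept in every omission. The retrotransposon rire8 had a change of −2.44 log2 at C1, lost without C1 replicate 2 (range −2.79 to −2.11), and osr2 rose by 1.64 log2 at C1, lost without C0 replicate 3 or C1 replicate 3. Calls numbered 734 at C1 (367 higher, 367 lower) and 289 at C3 (171 and 118), and most were gene probes (539 and 228). Spike-in scaling gave 19 higher and 201 lower at C1 and 21 and 43 at C3. At C5, limma called 0 probes, with 1900 at an unadjusted p under 0.05, while normexp and the matrix values each called 1, slide as a fixed block 38 and array weights 595. The C1 count was 1229, 342 and 259 without C1 replicates 1, 2 and 3, and 24 with slide as a fixed block. The C3 count was 183 without C0 replicate 1 and 109, 180 and 125 without C3 replicates 1, 2 and 3, and the C5 count was 2, 1 and 9 without C0 replicate 3, C5 replicate 1 and C5 replicate 3.

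In Silewah, osa-MIR160d, of the family that targets auxin response factors, rose by 1.38 log2 at C3 (standard error 0.29, adjusted p of the strain interaction 0.0303), kept in every omission. CI484934 was at least 6.40-fold higher at C3 and at least 6.90-fold at C1, also kept in every omission. Of the sense microRNA precursors, 7 were higher and 0 lower at C1. Calls numbered 1053 at C1 (481 higher, 572 lower), 612 at C3 (349 and 263) and 14 at C5 (10 and 4). Gene probes made up 660, 408 and 10 of these calls, and repeats 383, 197 and 2. Spike-in scaling gave 36 higher and 154 lower at C1, the matrix values 535 and 86 at C3 and normexp 116 and 132 at C3. At C5 quantile normalization gave 14 and 2, and normexp 9 and 2. The C1 count was 676 without C0 replicate 1 and 596 without C1 replicate 2, the C3 count 332 without C0 replicate 1, and the C5 count 47 without C0 replicate 3 and 9 without C5 replicate 2. With slide as a fixed block the counts were 338, 391 and 1579.

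**Figure D2:**
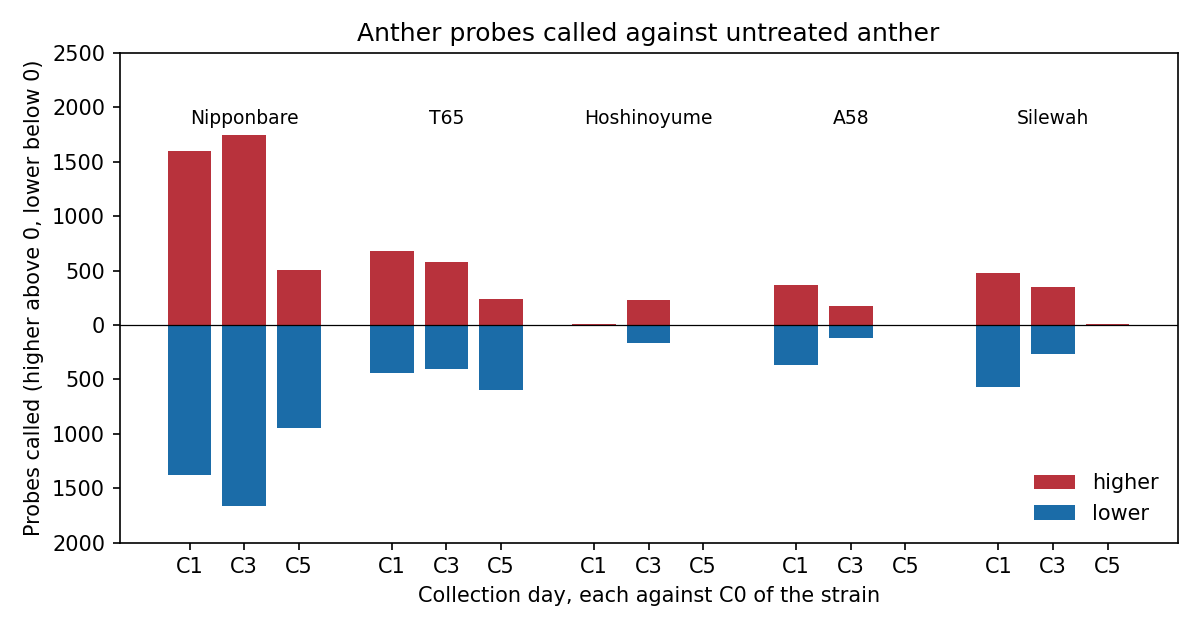
Number of probes called by limma (adjusted p under 0.05 and at least 2-fold) in each strain for C1, C3 and C5 against C0, with higher calls above 0 and lower calls below 0. Nipponbare has the most calls against C0 under this scaling, where T65 had more on the matrix values and with spike-in scaling, and at C5 against C0 Hoshinoyume has 1 call, A58 has 0 and Silewah has 14.

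The comparison of C5 with C3 set anthers 1 day after the return to warmth against anthers still in the cold. Os01t0600900-03 was higher at C5 by 2.71 log2 in Nipponbare, 4.39 in T65, 4.28 in Hoshinoyume, 2.08 in A58 and 3.95 in Silewah (standard error 0.55). AK060548 went down in 4 strains, with changes of −6.08, −5.65, −6.01 and −4.50 log2 in Nipponbare, Hoshinoyume, A58 and Silewah (standard error 0.98), kept in every omission. The MITE ORSgTEMT05200103 was lower in the same strains (−2.001, −2.89, −2.05 and −2.76 log2, standard error 0.39), also kept in every omission. Calls numbered 1409 in Nipponbare (1034 higher, 375 lower), 117 in T65 (75 and 42), 1656 in Hoshinoyume (1070 and 586), 942 in A58 (350 and 592) and 1591 in Silewah (1144 and 447). Of the slides that held both days, slide 16 (Nipponbare), 12 (T65), 9 (Hoshinoyume), 19 (A58) and 13 (Silewah) gave the same direction for 99.6% to 100% of the calls, which these arrays had entered, and at 2-fold or more for 77.1% to 95.9%. Os01t0600900-03 lost its A58 call without C3 replicate 1 or C5 replicate 3 (1.72 to 2.39 log2 over the omissions).

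The direction of the C5 against C3 calls depended on the scaling in Nipponbare, where spike-ins gave 538 higher and 693 lower and the matrix values 788 and 113, and in A58, where they gave 142 and 68, and 249 and 119, with normexp at 345 and 269. T65 had 77 higher and 7 lower with spike-ins and 44 and 8 on the matrix values, and Silewah 848 and 118 with spike-ins. Nipponbare had 552 calls without C3 replicate 1 and 2302, 411 and 153 without C5 replicates 1, 2 and 3. T65 had 54 without C3 replicate 3 and 52 and 47 without C5 replicates 1 and 3. A58 had 517 and 603 without C3 replicates 1 and 3 and 489 and 452 without C5 replicates 1 and 2. Silewah had 801 without C3 replicate 1 and 535 and 698 without C5 replicates 1 and 2.

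Of 1722 centromere repeat probes 707 were called higher at C5 than at C3 in Nipponbare (41.1%, against 3.22% of all probes), 619 in Hoshinoyume (35.9% against 3.34%), 371 in Silewah (21.5% against 3.57%), 33 in A58 (1.92% against 1.09%) and 2 in T65 (0.116% against 0.234%). The Nipponbare number depends on the arrays and the scaling. All classes together had as few as 153 calls there with 1 array left out, and 538 higher calls with spike-in scaling. The centromere satellite (code CMCM002, 1441 probes), singled out after its values were seen, was on average 1.02 log2 higher at C5 than at C3, by 1.51 in Nipponbare, 0.75 in T65, 1.27 in Hoshinoyume, 0.79 in A58 and 0.79 in Silewah. Against C0 its mean was lower at C1 (−0.51) and C3 (−0.49) and higher at C5 (0.53), in 5 of 5 strains each. In Nipponbare C5 minus C0 was 0.75 over all arrays but 0.08 within session 2 and 0.31 on slide 4, and C5 replicates 2 and 3 lay in session 3, which held no C0 array. In Hoshinoyume the C3 arrays stood at −4.12 ± 0.15 (SD, n = 3) and the C5 arrays at −2.85 ± 0.08, and in Nipponbare at −3.78 ± 0.46 and −2.27 ± 0.46. Silewah had −3.88 ± 0.18 and −3.09 ± 0.24. The spread was wide beside the rise in T65 (−3.52 ± 0.72 and −2.77 ± 0.20) and A58 (−3.16 ± 0.72 and −2.37 ± 0.55). Well above background were 73.0% of its values at C0, 59.7% at C1, 62.3% at C3 and 75.7% at C5. By exchange of arrays between days within strains the permutation p was 2e-05 for C5 against C3 (adjusted p 0.00044 over 44 tests), and the adjusted permutation p was 0.0160 at C1, 0.0199 at C3 and 0.00862 at C5 against C0. The exchange took no account of slides. The 44 tests covered sets fixed after the data had been seen, so the adjustment leaves out the families they were picked from. Outside Nipponbare no slide held C0 with C3 or C5, so the p-values for these days against C0 cannot tell day from slide. The rise from C3 to C5 had the same sign in all 5 strains under the other scalings (means 0.45 to 1.12), while C5 against C0 turned in 1 strain on the matrix values (−0.12). The centromere-specific retrotransposons (CMCM001) differed by 0.17 log2 on the antisense strand (adjusted permutation p 0.164) and 0.11 on the sense strand (0.446) between C5 and C3, and gene probes by 0.01.

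**Figure D3:**
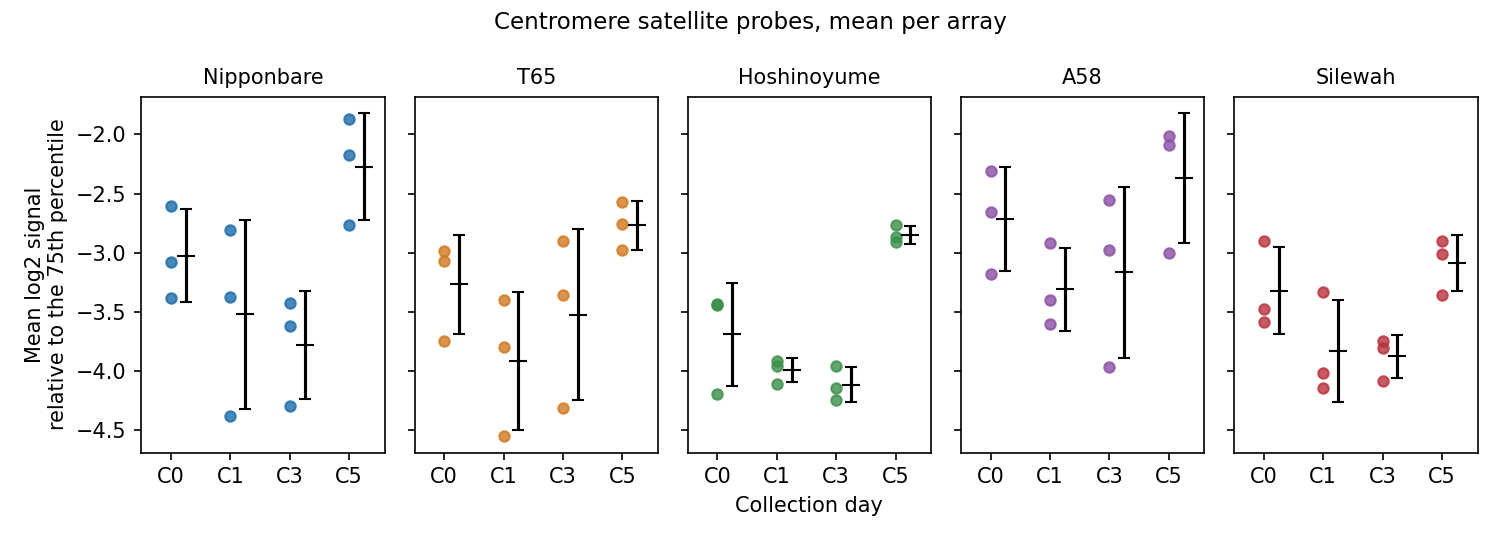
Mean normalized log2 signal of the 1441 centromere satellite probes on each anther array, by strain and day; points are arrays and bars the mean with the SD of 3 arrays. Mean C5 values exceed mean C3 values in all 5 strains, by 0.75 log2 in T65 to 1.51 in Nipponbare.

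Repeat probes changed on any day numbered 2672 in Nipponbare, 812 in T65, 768 in Hoshinoyume, 373 in A58 and 920 in Silewah, of 20783 tested. The OTOT repeats of T65 had 207 lower probes at C5, where the sense mean was −0.28 log2 and between −0.89 and −0.30 under the other scalings. All classes together had 0 T65 calls at C5 with slide as a random block, and as few as 12 with 1 array left out. Camera with a preset correlation called 125 of 378 shifts of 21 probe classes. Among them were the antisense CMCM probes at C5 in Nipponbare (mean 0.70 log2, adjusted p = 0.921 with an estimated correlation), and 0 of the 378 held with an estimated correlation. Without A58 C1 replicate 1, C1 replicates 2 or 3, or C5 replicates 1 or 2, A58 had 705, 218, 202, 242 and 212. Hoshinoyume had 417, 372 and 425 without C3 replicates 1, 2 and 3 and 301, 303 and 395 without C5 replicates 1, 2 and 3. T65 had 309 and 504 without C0 replicates 1 and 3, 1264 without C3 replicate 3, and 526 and 507 without C5 replicates 1 and 2. Silewah had 523 without C1 replicate 2 and 551 and 534 without C5 replicates 1 and 2, and Nipponbare had 1418 without C0 replicate 2 and 4018, 1678 and 1443 without C5 replicates 1, 2 and 3.

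Whether the response differed between strains was tested with interaction terms. CI484934 rose in A58 and Silewah and was called for the C3 interaction (adjusted p 0.0012). osa-MIR2864 rose in Silewah at C3 by 1.13 log2 (adjusted p of the interaction 0.00507), osa-MIR156d in T65 (0.0433), AK063797 in Hoshinoyume (0.0303) and osa-MIR160d in Silewah (0.0303). ORSiRGRR00000355, a ribosomal DNA probe, changed by −3.00 log2 in Nipponbare at C3 (standard error 0.53) and was called for the interaction (adjusted p 0.043). The 4 MIR2118 precursors named by the rule were not called, with adjusted p of 0.0685 to 0.339. In all, 791 probes differed at C1, 652 at C3, 856 at C5 and 960 over all days, and of the 652, 428 had Nipponbare farthest from the mean of the other strains, 96 T65, 82 Silewah, 24 A58 and 22 Hoshinoyume. Among OTOT repeats 219 of 1096 (19.98%) were called at C3, among gene probes 201 of 10789 (1.86%). Without Nipponbare in the fit the counts were 207, 33, 113 and 201, with scan session as a block 552, 159, 540 and 1016, and with slide as a random block 45, 5, 28 and 16.

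Leaving out 1 array moved the interaction counts as well. The count over all days was 1539 without A58 C1 replicate 1, 1853, 1728 and 1855 without Nipponbare C1, C3 and C5 replicate 1, 1677 without Silewah C3 replicate 3, 1480 without T65 C1 replicate 3 and 611 without T65 C0 replicate 1. At C1, Nipponbare arrays gave 1293 and 484 (C0 replicates 1 and 2) and 2468, 150 and 209 (C1 replicates 1, 2 and 3). T65 arrays gave 429 and 484 (C0 replicates 1 and 3) and 449, 381 and 2317 (C1 replicates 1, 2 and 3), A58 arrays 1709 and 518 (C1 replicates 1 and 2), Hoshinoyume C1 replicate 1 gave 1310 and Silewah C0 replicate 1 gave 496. At C3, Nipponbare arrays gave 999 and 55 (C0 replicates 1 and 2) and 2120, 53 and 61 (C3 replicates 1, 2 and 3). T65 arrays gave 122 and 138 (C0 replicates 1 and 3) and 102, 134 and 1379 (C3 replicates 1, 2 and 3), and Silewah arrays 104, 1211 and 291 (C0) and 128, 192 and 1352 (C3, replicates 1, 2 and 3 each). A58 C3 replicates 1, 2 and 3 gave 153, 218 and 229, Hoshinoyume C0 replicate 1 gave 375 and its C3 replicates 2 and 3 gave 233 and 244. At C5, Nipponbare arrays gave 1408, 365 and 1480 (C0) and 2611, 323 and 237 (C5, replicates 1, 2 and 3 each). T65 arrays gave 158 and 452 (C0 replicates 1 and 3) and 281, 232 and 537 (C5 replicates 1, 2 and 3), A58 C0 replicate 2 and C5 replicate 2 gave 1413 and 538, and Silewah arrays 1379 (C0 replicate 2) and 546 and 565 (C5 replicates 1 and 2).

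Untreated anthers of the 5 strains differed for 8267 of 32063 probes. The precursor osa-MIR416 was at least 22.7-fold higher in Silewah than in A58 and osa-MIR441c at least 20.7-fold higher in A58 than in T65 (12.7-fold without A58 C0 replicate 3). osa-MIR2118h was at least 4.46-fold higher in Nipponbare than in Silewah, but 1.38-fold without Nipponbare C0 replicate 3, and the lower strain was well above background on 0 of 3 arrays in each case. Silewah was farthest from the other strains for 3263 of the probes, Nipponbare for 1625, A58 for 1599, T65 for 1002 and Hoshinoyume for 778. The share called was 39.4% for retrotransposon probes (TERT), 34.3% for OTOT, 32.2% for transposons, 29.3% for MITEs, 23.8% for centromere repeats and 17.8% for genes. Sequence differences between the strains under the probes were not examined, and each strain was scanned in sessions of its own. The count was 13225 on the matrix values, 3950 with normexp and 4807 with slide as a random block.

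Leaf and anther were compared in untreated Nipponbare and T65. osa-MIR2925 on the antisense strand was 8.62 log2 higher in leaf in Nipponbare and 7.27 in T65 (standard error 0.73), and osa-MIR159a 5.71 in Nipponbare (standard error 0.37) and at least 18.1-fold in T65. osa-MIR2118o was lower in leaf (−6.21 and −6.32 log2, standard error 0.55), but most of its family was not called. Of 17 sense MIR2118 precursors tested, 2 were lower and 0 higher in leaf in Nipponbare (median −1.68 log2). In T65 1 was lower and 1 higher (median −0.003). CP1 was at least 16.4-fold and 20.8-fold lower in leaf. GAMYB (−2.17 and −1.81 log2, standard error 0.19) and DCL3b (−2.65 and −2.30, standard error 0.37) were also lower in leaf in both strains. Of the gene probes 1863 were higher and 1953 lower in leaf in both strains, among 10825 tested. All these named calls were kept in every omission of an array.

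Probes called between leaf and anther numbered 9297 in Nipponbare (4442 higher in leaf, 4855 lower) and 10531 in T65 (5844 and 4687). Both strains shared 3376 higher calls (822 expected for independent lists) and 2875 lower calls (721 expected), and the log2 differences correlated with r 0.856 across probes. Scaled to spike-ins the splits were 3395 and 6757 in Nipponbare and 3066 and 10219 in T65, where the matrix values gave 2612 and 11730. The difference itself differed between the strains for 1021 probes, 665 with a higher leaf value relative to anther in T65 and 356 with a lower one. This split turned under each other scaling, to 293 and 478 with quantile normalization, 84 and 258 with normexp, 35 and 597 on the matrix values and 104 and 321 with spike-ins. PRR1 was 2.28 log2 higher in leaf in Nipponbare and 0.78 in T65, where it was not called, and the difference between the strains was not past the threshold (adjusted p 0.178). The interaction count was 963 with slide as a random block. It was 60 with the replicate number as a block. The numbers were not taken to pair the samples, but pairing was not excluded. With 1 array left out it was 371 without Nipponbare C0 replicate 2, 399, 393 and 613 without Nipponbare leaf replicates 1, 2 and 3, 257, 461 and 369 without T65 C0 replicates 1, 2 and 3, and 655, 350 and 595 without T65 leaf replicates 1, 2 and 3.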

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

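The tests of Nipponbare against scaling, scan session and its untreated replicates were chosen only after the result was seen, as was the extension of the draws from 40 or 60 to 100, while the splits of the samples themselves were planned.

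The response to cool treatment differed between strains for 960 probes over all days, 791 at C1, 652 at C3 and 856 at C5, which drew attention because an interaction test was passed. Of 100 draws with the residuals exchanged within strains, the real one included, 2 gave as many probes over all days (highest other draw 1257). At C1 it was 1 draw (685), at C3 2 (1650) and at C5 2 (1448). Each share was under 0.05, but the draws took no account of slides. They thus cannot exclude chance for arrays that vary together within slides. With slide as a random block (correlation within slides 0.286) the counts fell to 16, 45, 5 and 28, in the same order. Of the first 60 draws the numbers were 2, 1, 2 and 1. The draw with 1650 probes at C3, far above the real count, points to a structure of the arrays other than strain and day. Strain and scan session run together here, so a difference between strains cannot be told apart from one between sessions.

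The difference between leaf and anther differed between Nipponbare and T65 for 1021 probes, again by an interaction test. Of 100 draws only the real one gave as many, and the highest other draw gave 0. These draws took no account of slides or replicate numbers. The count was 963 with slide as a random block and 60 with the replicate number as a block. Untreated strain differences, 8267 probes, were reached by 1 of 100 draws, with 5752 in the highest other.

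Nipponbare anthers had the most called probes against C0, 2979 at C1, 3414 at C3 and 1455 at C5, under the main scaling and with quantile normalization or normexp. Untreated replicates that differ from each other stay open on each day. At C3 the count stayed at 1378 or more without each C0 array in turn, above another strain's highest (984, T65). At C1 the lowest, 1274, stood above T65 (1123) and below Silewah without its C0 replicate 3 (1490), and at C5 513 fell below T65 (837). These omissions cannot decide the question at C3, because the remaining C0 arrays still differ and the spread came from all groups. The wide spread of Nipponbare C0 (median SD 0.417) thus entered only in part. With only the arrays compared, Nipponbare had 10 calls at C3 against 622 in Hoshinoyume. Scaling of the arrays stays open, since under 2 of 4 other scalings T65 had more on each day, with 4333, 4612 and 2718 against 1753, 2101 and 169 on the matrix values and 1795, 1022 and 98 against 1759, 955 and 13 with spike-ins, and another strain also led with array weights, slide as a fixed block or only the arrays compared. Scan session stays open too, because with a block for it T65 had more at C1 (1590 against 1469) and C5 (1091 against 65), and at C3, where Nipponbare had 2174 against 1198, its count was 58 to 3731 without 1 of its 12 arrays, while the median size of the called changes fell from 1.47 to 1.25 log2 at C1 (ratio 0.848, standard error 0.41 before and 0.49 after), from 1.52 to 1.31 at C3 and from 1.40 to 0.93 at C5 (ratio 0.659, standard error 0.39 and 0.40), and 735 of 2979, 864 of 3414 and 52 of 1455 probes kept a call, at C5 because the changes were smaller. A stronger response of this strain stays among the open explanations, as untested, because session and strain overlap in the design.

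For 3 against 3 arrays there are 10 splits and the share is never under 0.1, so they are too few to exclude chance. The numbers of splits as large as the real one, itself included, follow in the order C1, C3 and C5 against C0 and C5 against C3, with the real count and the highest other. Nipponbare had 1 (2979, highest other 2219), 1 (3414, 1107), 3 (1455, 2620) and 2 (1409, 1673). In T65 there were 1 (1123, 3), 1 (984, 2), 1 (837, 1) and 1 (117, 2). Hoshinoyume gave 4 (16, 559), 1 (395, 3), 9 (1, 15) and 1 (1656, 3). For A58 the numbers were 1 (734, 179), 1 (289, 0), 10 (0, 4) and 1 (942, 0). Silewah had 1 (1053, 156), 2 (612, 1805), 1 (14, 9) and 1 (1591, 4). Leaf against anther gave 1 in Nipponbare (9297, 0) and 1 in T65 (10531, 0).

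Some of these splits follow a batch or point to a structure of the arrays. In Nipponbare the split with 2620 probes set the arrays of scan session 2 (C5 replicate 1 with C0 replicates 2 and 3) against the rest, and with session as a block the C5 count was 65. For C5 against C3 the split with 1673 probes put the arrays outside session 3 (C5 replicate 1 and C3 replicate 1) together with C3 replicate 2, and within session 3, whose arrays had entered the fit, all 1409 calls (100%) had the same direction and 95.9% did so at 2-fold or more. In Hoshinoyume the split with 559 probes set C1 replicates 1 and 2 and C0 replicate 3 against the others, and in Silewah the split with 1805 probes did so for C3 replicates 1 and 2 and C0 replicate 2. Both call several times the real count within 1 scan session.

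Repeat probes changed on any day numbered 2672 in Nipponbare (2 of 100 splits as large, highest other 3111), 812 in T65 (3, 1960), 768 in Hoshinoyume (1, 678), 373 in A58 (2, 558) and 920 in Silewah (1, 908). The share was under 0.05 in Nipponbare, Hoshinoyume, A58 and Silewah, and in T65 only after the draw was extended. Of the first 40 splits 1, 2, 1, 1 and 1 were as large, and 2 of 40 is not under 0.05. These splits took no account of slides, so they cannot exclude chance for arrays that vary together within slides. With slide as a random block the counts were 1655, 58, 467, 387 and 858, in the same order. The T65 split with 1960 probes, far above the real count, also points to a structure of the arrays.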

How the results depend on the processing

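Spike-in scaling, scan session as a block, the leading within-group component, the omission of Nipponbare, gene by gene array weights, the pairing of leaf with anther and the omission of arrays for named probes were chosen after the results were seen, and the others were planned. Of 34 counts, 32 stayed within 1.5 times the main count with quantile normalization and 33 with the stricter filter, against 6 with array weights and 9 with normexp or with the matrix values. The cause of the changes was not tested, apart from the fewer arrays in a fit and the smaller or larger number of probes tested (27539 with the stricter filter, 43788 without a filter in anther). Of 247 named calls, 239 kept their direction and an adjusted p under 0.05 with quantile normalization, 208 with normexp, 191 on the matrix values, 147 with spike-in scaling, 164 with slide as a random block and 28 of the 78 Nipponbare calls with scan session as a block. These counts, and the one with slide as a fixed block, asked for no 2-fold change, unlike the omissions of 1 array. Leaving out 1 array at a time, 117 named calls were kept in every omission, 130 were lost in at least 1 and 0 turned sign. With slide as a fixed block 81 of 208 were kept and 2 values turned sign, those of osa-MIR159f at C3 (0.34 log2) and AK072708 at C1 (−0.24 log2), both in Nipponbare. Signal over background limits what is seen of dim probes, since 52.58% to 75.63% of probes were well above it.

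With array weights, Nipponbare had 3320 at C5, 4978 for C5 against C3 and 5805 for repeats on any day. T65 reached 4681 at C1, 4776 at C3, 4250 at C5, 2114 for C5 against C3 and 4450 for repeats on any day. Hoshinoyume stood at 1028 at C1, 3374 at C3, 1191 at C5, 3304 for C5 against C3 and 2394 for repeats on any day. A58 gave 3442 at C1, 1676 at C3, 595 at C5, 3952 for C5 against C3 and 2325 for repeats on any day. Silewah had 2333 at C1, 3022 at C3, 876 at C5, 3007 for C5 against C3 and 2652 for repeats on any day. The count was 19111 for the interaction over all days, 11074 for the C1 interaction, 11206 for the C3 interaction, 11044 for the C5 interaction and 13720 for untreated strain differences. The weights ranged from 0.176 to 8.18 in anther.

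With normexp and quantile normalization, Nipponbare had 1485 at C1, 1714 at C3, 914 for C5 against C3 and 1097 for repeats on any day. T65 reached 462 at C1, 463 at C3, 481 at C5 and 161 for repeats on any day. Hoshinoyume stood at 238 at C3, 952 for C5 against C3 and 200 for repeats on any day. A58 gave 401 at C1, 190 at C3, 1 at C5, 614 for C5 against C3 and 62 for repeats on any day. Silewah had 466 at C1, 248 at C3, 726 for C5 against C3 and 101 for repeats on any day. The count was 380 for the C5 interaction, 3950 for untreated strain differences, 5910 for Nipponbare leaf, 6670 for T65 leaf and 342 for the strain by tissue interaction. With quantile normalization, Hoshinoyume had 7 at C1 and 11 at C5.

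With the authors' matrix values, Nipponbare had 1753 at C1, 2101 at C3, 169 at C5, 901 for C5 against C3 and 1152 for repeats on any day. T65 reached 4333 at C1, 4612 at C3, 2718 at C5, 52 for C5 against C3 and 3004 for repeats on any day. Hoshinoyume stood at 71 at C1 and 115 at C3. A58 gave 269 at C1, 104 at C3, 1 at C5 and 368 for C5 against C3. Silewah had 429 at C1, 9 at C5 and 724 for C5 against C3. The count was 637 for the interaction over all days, 372 for the C1 interaction, 982 for the C3 interaction, 1410 for the C5 interaction, 13225 for untreated strain differences and 632 for the strain by tissue interaction.

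With spike-in scaling, Nipponbare had 1759 at C1, 955 at C3, 13 at C5 and 1332 for repeats on any day. T65 reached 1795 at C1 and 98 at C5. Hoshinoyume stood at 4 at C1, 79 at C3 and 0 at C5. A58 gave 220 at C1, 64 at C3 and 210 for C5 against C3. Silewah had 190 at C1, 60 at C3, 6 at C5 and 966 for C5 against C3. The count was 539 for the interaction over all days, 518 for the C1 interaction, 106 for the C3 interaction, 29 for the C5 interaction and 425 for the strain by tissue interaction.

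With slide as a random block, Nipponbare had 1607 at C1, 1955 at C3, 272 at C5 and 1655 for repeats on any day. T65 reached 63 at C1, 109 at C3, 0 at C5, 188 for C5 against C3 and 58 for repeats on any day. Hoshinoyume stood at 0 at C1, 0 at C5 and 467 for repeats on any day. A58 gave 381 at C1 and 83 at C3. Silewah had 281 at C3 and 2 at C5. The count was 16 for the interaction over all days, 45 for the C1 interaction, 5 for the C3 interaction, 28 for the C5 interaction and 4807 for untreated strain differences. The correlation within slides was 0.286 in anther and 0.0107 in leaf. With slide as a fixed block, Nipponbare had 1 at C1, 337 at C3, 255 at C5 and 1080 for repeats on any day. Hoshinoyume reached 93 at C1, 12 at C5 and 933 for C5 against C3. A58 stood at 24 at C1, 38 at C5 and 1068 for repeats on any day. Silewah gave 338 at C1, 391 at C3, 1579 at C5, 2421 for C5 against C3 and 2796 for repeats on any day.

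Replicate numbers were not taken to pair the samples, because not every pair of arrays with the same number correlated over 0.1. This rule cannot exclude pairing, since the mean r was higher for the same number than for different numbers in each strain, most of all in T65. Pairs over 0.1 numbered 14 of 18 with the same number and 5 of 36 with different numbers in T65, and the mean r of same and different numbers was 0.29 and −0.14 there, 0.12 and −0.05 in Nipponbare, 0.02 and −0.01 in Hoshinoyume, 0.14 and −0.07 in A58 and 0.12 and −0.06 in Silewah. Untreated leaf and anther arrays of the same number had r of 0.14, 0.04 and 0.04 in Nipponbare, where each pair shared a slide, and 0.13, 0.00 and 0.08 in T65, where none did. Deviations of anther arrays with the same number correlated with r between −0.41 and 0.78 over pairs of days, and of 12 arrays per strain 8 were closest to their own number on every day in T65, 3 in A58, 2 in Silewah, 1 in Nipponbare and 0 in Hoshinoyume. With the replicate block, Nipponbare had 2616 at C5. T65 reached 1934 at C1, 1500 at C3, 1517 at C5, 570 for C5 against C3 and 1766 for repeats on any day. Hoshinoyume stood at 87 at C1, 604 at C3 and 472 at C5. A58 gave 1824 for C5 against C3 and 744 for repeats on any day. Silewah had 1696 at C1, 1210 at C3, 23 at C5 and 1498 for repeats on any day. The count was 2106 for the interaction over all days, 2222 for the C1 interaction, 1791 for the C3 interaction, 2541 for the C5 interaction and 60 for the strain by tissue interaction. A block for the number shared across strains gave 8740 untreated strain differences.

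With only the arrays compared in the fit, Nipponbare had 7 at C1, 10 at C3, 0 at C5, 595 for C5 against C3 and 325 for repeats on any day. T65 reached 302 at C1, 290 at C3, 1316 at C5, 31 for C5 against C3 and 385 for repeats on any day. Hoshinoyume stood at 0 at C1, 622 at C3, 0 at C5 and 509 for repeats on any day. A58 gave 2 at C1, 141 at C3 and 1857 for C5 against C3. Silewah had 4 at C1, 1 at C3 and 0 at C5. The count was 71 for the C1 interaction and 4 for the C3 interaction. With the leading within-group component as covariate, Nipponbare had 2580 at C5. T65 reached 2108 at C1, 1571 at C3 and 124 at C5. Hoshinoyume stood at 30 at C1 and 702 at C3. A58 gave 1571 for C5 against C3 and 660 for repeats on any day. Silewah had 1310 at C3 and 33 at C5. The count was 1759 for the C1 interaction and 254 for the C3 interaction.

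With scan session as a fixed block, Nipponbare had 1469 at C1, 2174 at C3, 65 at C5 and 1443 for repeats on any day. The count was 159 for the C3 interaction and 540 for the C5 interaction. With Nipponbare left out of the fit, the count was 201 for the interaction over all days, 207 for the C1 interaction, 33 for the C3 interaction and 113 for the C5 interaction. With no filter on dim probes, Nipponbare had 2225 at C5. Hoshinoyume reached 2 at C5. The count was 360 for the C3 interaction, 13794 for untreated strain differences, 15804 for T65 leaf and 1705 for the strain by tissue interaction. With the stricter filter, the count was 549 for the strain by tissue interaction.

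With each array left out in turn, an arm kept 2 arrays and the spread came from all groups. In Nipponbare the range was 1274 to 4310 at C1, 1343 to 4619 at C3, 131 to 4123 at C5, 1418 to 4018 for repeats on any day and 153 to 2302 for C5 against C3. In T65 the range was 592 to 1714 at C1, 459 to 1695 at C3, 12 to 1068 at C5, 309 to 1264 for repeats on any day and 47 to 131 for C5 against C3. In Hoshinoyume the range was 0 to 496 at C1, 72 to 809 at C3, 4 to 29 at C5 and 301 to 1062 for repeats on any day. In A58 the range was 259 to 1229 at C1, 109 to 222 at C3, 0 to 9 at C5, 202 to 705 for repeats on any day and 452 to 1177 for C5 against C3. In Silewah the range was 596 to 1490 at C1, 332 to 878 at C3, 9 to 47 at C5, 523 to 1310 for repeats on any day and 535 to 1449 for C5 against C3. It was 611 to 1855 for the interaction over all days, 150 to 2468 for the C1 interaction, 53 to 2120 for the C3 interaction, 158 to 2611 for the C5 interaction and 257 to 1169 for the strain by tissue interaction. The ranges 7513 to 9416 for untreated strain differences, 7514 to 9614 for Nipponbare leaf, 9205 to 10185 for T65 leaf and 1210 to 1401 for C5 against C3 in Hoshinoyume stayed within 1.5 times the main count.

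The median log2 change of all probes moved by over 0.1 under some scalings. On the matrix values it was −0.04, −0.04 and 0.00 in Nipponbare at C1, C3 and C5 (main −0.14, −0.15 and −0.18), −0.33 in Hoshinoyume at C1 (−0.04), 0.18 in A58 at C5 (−0.11) and 0.12 there for C5 against C3 (−0.10), and 0.18 and 0.26 in Silewah at C3 and C5 (0.02 and 0.04). With spike-ins it was 0.15, 0.03 and −0.36 in Nipponbare and −0.42 for C5 against C3 (−0.06), −0.43, −0.42 and −0.17 in T65 and 0.20 for C5 against C3 (0.01), −0.24 and −0.13 in Hoshinoyume at C1 and C5 and −0.17 for C5 against C3, −0.15 and −0.13 in A58 at C1 and C3 and 0.00 for C5 against C3, and 0.14 and 0.24 in Silewah at C3 and C5. Normexp gave −0.05 and −0.07 in Nipponbare at C3 and C5 and 0.04 in T65 at C5 (0.16).

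The number of class shifts called by camera, 125 of 378, lay between 91 and 175 under the other settings and was 0 with an estimated correlation. The mean of the probes of a gene, slide as a fixed block for T65 against C0, T65 leaf, the interactions and untreated strain differences, fits of only the arrays compared for the interactions over all days and between tissues, and the class shifts with slide as a block were not run. Where compared groups shared no slide, as for C3 against C0 in Nipponbare and Silewah, the fixed block linked them only through slides of other days.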

Other observations

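The tests of the centromere satellite, of array brightness and of scan session were chosen only after the result was seen, as were the leaf values and the other gene probes set beside the test of green tissue, which was itself written before.

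The antisense probe of the transposon ORSgTETNOOT02079 was at least 3.01-fold higher in Nipponbare at C3 (above background on 1 of 3 arrays there and on 0 at C0) and rose by 3.26 log2 in A58 at C1 (standard error 0.74). It was at least 2.002-fold lower at C5 than at C3 in Hoshinoyume and 4.21-fold lower in A58, and all 4 calls were kept in every omission. The transposon ORSgTETN00100112 (antisense) was higher at C5 than at C3 by 2.09 log2 in A58 (standard error 0.46) and at least 1.95-fold in Silewah, also kept in every omission. The telomere-associated repeat ORSiTRTA00000012 had a change of −1.82 log2 in Nipponbare at C1, kept in every omission, and −1.10 at C3, lost in 3 of 6. The retrotransposon osr39 was lower in Nipponbare at C1 (−2.24 log2, standard error 0.67), a call lost without C0 replicate 2, C1 replicate 2 or C1 replicate 3 (−1.37 at the smallest). osr6 was at least 3.50-fold higher in A58 at C1, lost without C1 replicate 2 or 3. osa-MIR399j, of a family tied to phosphate supply, rose by 3.94 log2 in Nipponbare at C1 (standard error 1.15), lost without C0 replicate 2, and by 3.43 at C3, lost in 5 of 6 omissions.

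The centromere satellite rose between C3 and C5 in all 5 strains, by 1.02 log2 on average. Scaling of the arrays is argued against, since the lowest strain difference over 4 other scalings was 0.288, and so is slide, since the lowest difference between arrays of both days on 1 slide was 0.654. A general rise of dim repeat probes is argued against because the highest mean change among 200 sets of other repeat probes matched on signal was −0.0356 log2. Those sets mix families, so they cannot show how far the mean of 1 family may move between arrays. The mean of the MITE family TEMT017 deviated by −0.54 to 0.70 log2 within groups. Among what stays open is a hypothesis found and tested on the same data, that transcripts of the centromere satellite may be lowered in the cold and accumulate after the return to warmth. The stage of the anthers also differs between C3 and C5, so development cannot be told apart from treatment.

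Probes of the MITE family TEMT017 (2529 probes) varied together between replicates of a group, with deviations of −0.54 to 0.70 log2 from the group mean and the highest SD, 0.61, in Nipponbare C3. Array brightness is argued against, as its correlation with the family mean over 60 anther arrays was r −0.146 (permutation p 0.427, rho −0.13, permutation p 0.42, r −0.18 without the 2 farthest arrays). Admixture of green tissue needs a positive relation with the 1645 gene probes higher in leaf. That correlation was r −0.656 (permutation p 4e-05, adjusted p 8e-05 over 2 relations, rho −0.68, permutation p 2e-05, r −0.66 without the 2 farthest), the outcome set beforehand as arguing against admixture. The family was higher in leaf by a median of 0.24 log2 in Nipponbare and 0.65 in T65, but the 9144 other gene probes gave r −0.54 as well. The negative relation is thus not particular to leaf genes, and admixture was not decided by it. Scan session is argued against in the other strains, where groups lie in 1 session and the SD reached 0.466 in A58 C0 on 1 slide, but stays open in Nipponbare, where session took up a share of 0.671 of the spread within groups (as large in 3 of 81 arrangements, permutation p 0.0370), C3 standing at −0.80 in session 1 and −1.82 and −1.89 in session 3 and C5 at −1.18 in session 2 and −2.22 and −2.10 in session 3, but C0 at −1.83 in session 1 and −1.97 and −1.21 in session 2 and C1 at −1.49 in session 1 and −1.86 and −1.54 in session 3, without such a split. No biological explanation was tested.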
